A study of Rattus norvegicus with 12 samples.

How the data were processed

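RNA of cultured rat neural stem cells (NSCs) was measured on 12 Affymetrix Rat230_2 expression arrays, a platform on which each probe set is a group of short probes against the 3' part of a transcript. The cells came from brain or spinal cord of Sprague Dawley rats 3 to 5 days after birth, and each tissue was profiled in a proliferative and in a differentiated state, giving 4 groups of 3 arrays. Sample titles mark the differentiated groups with "fenhua", the romanised Chinese word for differentiation, and the series title names the 2 states. How the cells were differentiated, and for how long, is not given in the sources used here. Nothing says that the 3 arrays of a group came from separate cultures or animals, so the p-values measure only the spread between these arrays, which may be technical.

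Per the labels' protocols, total RNA was taken with TRIZOL, cleaned on columns with DNase digestion, checked on a Bioanalyzer and turned into biotin-labelled cRNA with a 3' IVT kit. The submitters' processing notes name MAS5, which summarises and scales each array on its own, and affy, both without a version. The deposited values are log2 signals per probe set, read from the series' value table. Their centring and scale were worked out from the values: after conversion to the linear scale the mean of each array, with the upper and lower 2% trimmed, was 500, the target scaling that MAS5 uses, and genes had not been centred. Detection calls and scanner files were not used here. Array medians lay between 6.88 and 7.23, and the highest value of an array between 14.8 and 15.2. The 3' minus 5' signal, a sign of RNA quality, was -0.13 to 0.13 for Gapdh and did not overlap between the states in brain. For Actb it was 0.99 to 1.01 on differentiated spinal cord arrays, 0.69 to 0.99 on proliferative ones, 0.73 to 0.81 on differentiated brain arrays and 0.77 to 0.84 on proliferative ones. Negative control probe sets for bacterial TrpnX averaged 0.78 to 2.72 per array, with a highest single value of 3.93. The 5S rRNA control was 9.50 to 11.02 on proliferative and 7.85 to 8.19 on differentiated brain arrays, and 8.65 to 9.38 and 8.09 to 8.75 on the spinal cord arrays.

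The table held 31099 probe sets, of which 57 controls were left out. A probe set was tested if at least 3 of the 12 arrays had it above that array's own 40th percentile, which kept 20834 of 31042. The platform annotation gave 1 gene symbol to 20826 probe sets, several to 436 and none to 9780. Of those with 1 symbol, 20758 matched a current rat gene (assembly GRCr8, used for names only) by Entrez ID. No genome was given, so no positions are printed. The probe set with the highest mean over the 12 arrays stood for its gene, giving 14217 genes, 11218 of them tested. Among 3316 genes with more than 1 tested probe set, those with calls in opposite directions numbered 43 for brain differentiation, 32 for spinal cord differentiation, 7 and 32 for the tissue contrasts in proliferative and differentiated cultures, and 25 for the difference of responses.

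All contrasts came from 1 linear model with a mean per group, fitted to the 12 arrays with limma (lmFit, then eBayes with a mean-variance trend; 8 residual degrees of freedom) in R 4.3.3 with limma 3.58.1; figures were drawn in Python 3.11.15. The contrasts were differentiated against proliferative cultures in brain and in spinal cord, spinal cord against brain in each state, and the difference between both differentiation responses, spinal cord minus brain. Adjusted p-values are Benjamini-Hochberg over all probe sets tested in a contrast, with a threshold of 0.05. A gene or list is said to rise, fall, differ or change only where it passed. Errors on group means are SD with n = 3, and the number of arrays limits their precision. The filter, model, lists and naming rule were fixed before the data were examined.

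MAS5 log2 values of dim probe sets spread widely and have no reliable order. Where all 3 arrays of a group lay under their own 40th percentiles (5.91 to 6.41), that group was called dim for the gene. A fold against it is written as "at least", from the bright group's mean minus the mean of those percentiles, and no fold is given where both groups were dim. This floor was chosen after seeing the data. A fold so bounded understates the change. A difference of responses is bounded in the same way where every dim group would only add to it, and no size is given where a dim group could take from it. A list's median is also given with dim groups set at that floor where this moved its fold or its log2 value by over 1.5 times, or turned its sign.

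The 26 gene lists were tested with camera with a preset inter-gene correlation of 0.01, Benjamini-Hochberg over the lists of a contrast. Camera was run on the deposited values, so its p-values do not belong to medians with dim groups at the floor. Each count of members up and down is followed by the count adjusted over the list alone. They covered neural stem and progenitor cells, DNA replication, mitosis, neurogenic transcription factors, neurons, astrocytes, oligodendrocyte precursors, mature oligodendrocytes, microglia and macrophages, endothelial cells, fibroblasts with meningeal and mural cells, Schwann cells, ependymal cells with motile cilia, erythroid cells, Hox genes, forebrain patterning factors, spinal progenitor factors, the Notch, Wnt, BMP and hedgehog pathways, cholesterol biosynthesis, interferon response, hypoxia and glycolysis, immediate early genes, and the unfolded protein and amino acid stress response. With an estimated correlation the calls that held were Hox genes, mature oligodendrocytes and oligodendrocyte precursors between proliferative tissues, and neural stem and progenitor cells, Hox genes, fibroblasts and ependymal cells between differentiated tissues.

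Genes named in the text follow a rule. For each contrast of 2 groups it takes the 10 largest rises and 10 largest falls among called genes whose 3 and 3 values did not overlap, which chance gives 10% of the time, and whose higher mean was above the median of tested probe sets; for the difference of responses it takes 5 in each direction without the overlap condition. For each list it takes the 4 called members with the largest change, or the 2 with the smallest p where none was called. It always takes Nes, Sox2, Mki67, Tubb3, Dcx, Gfap, Mbp, Olig2, Pdgfra and Hoxc8 where measured, and 1 further gene that is not reported here. Provisional symbols were passed over. The text names a part of these genes.

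The model and the list test were tested on simulated data with known changes before use. For brain differentiation, 50 of 20834 probe sets were changed at each size of change per run, in 5 runs. These were far fewer than the probe sets called in the data. Of the changes of 1.5-fold 19.2% were called, 62.0% of 2-fold, 84.4% of 4-fold and 92.4% of 8-fold, and 4.02% of calls were false. For the difference of responses the shares were 4.4%, 27.2%, 70.8% and 88.4%, with 3.44% false. A shifted list was called by camera with an adjusted p = 1.31e-60, and 0 of 25 unshifted lists were. The simulated genes were drawn independently of each other, so this run cannot tell whether the preset correlation of 0.01 holds in the data. Lists in the data had estimated correlations up to 0.70. Alternatives, whose effect the closing section gives, were quantile normalization, median centring, no filter or one at the 60th percentile, a model without the trend, array weights, pseudocounts of 16 and 64, the replicate number as a block, only the arrays of the groups compared, the mean over a gene's probe sets, every other probe set of a named gene, estimated list correlation, fry, and leaving out each array in turn. Median centring shifted the median change of all probe sets by -0.15 in brain differentiation, 0.08 in spinal cord differentiation, -0.21 between proliferative tissues, 0.02 between differentiated tissues and 0.23 for the difference of responses, and quantile normalization shifted it by -0.06, 0.05, -0.10, 0.01 and 0.11. Changes below are on the deposited scale.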

Results

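Gene expression was profiled in NSCs grown from the brain and the spinal cord of newborn rats, in a proliferative and in a differentiated state, with 3 arrays for each of the 4 groups. NSCs are cells that divide in culture and can give rise to neurons, astrocytes and oligodendrocytes, and the series compares the states within each tissue and the tissues within each state. Median log2 signals of the arrays ran from 6.88 to 7.23. Of 20834 probe sets tested, between 7877 and 9763 differed in each contrast of 2 groups. Arrays of a group correlated at r = 0.940 to 0.975 across probe sets, which are not independent replicates, and arrays of different groups at 0.735 to 0.880. The first principal component held 44.9% of the variance, the second 21.9% and the third 15.9%. One array stood apart within its group: in spinal cord proliferative replicate 1 the mean log2 signal of the mitosis list was 10.7, against 9.85 and 9.98 in replicates 2 and 3, and that of the DNA replication list was 10.4, against 9.39 and 9.50. Levels below are log2 signals given as mean ± SD over 3 arrays, and p-values are limma's, adjusted over all probe sets tested.

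**Figure D1:**
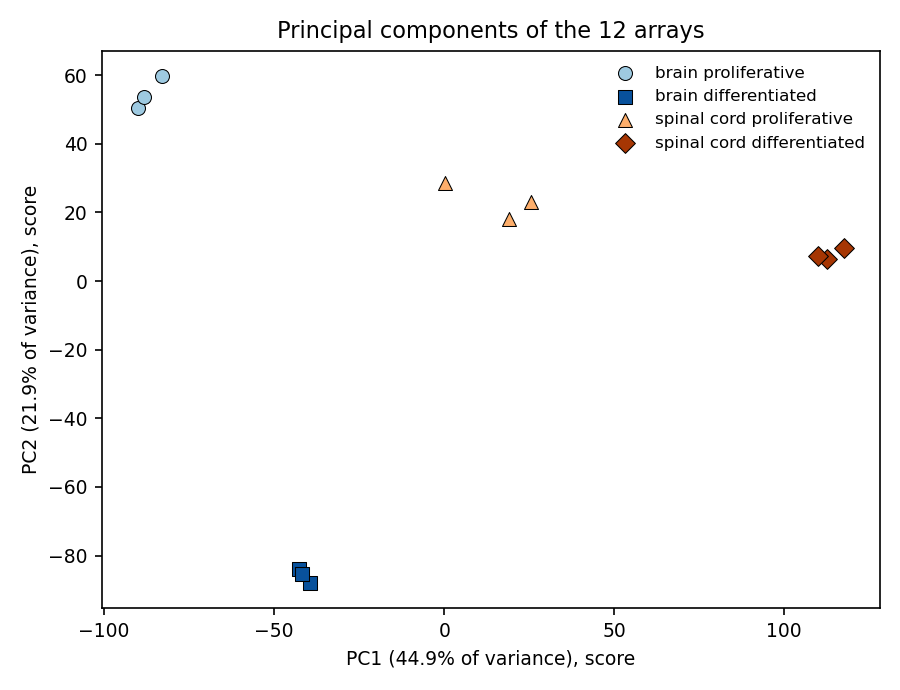
Scores of the 12 arrays on the first principal component (44.9% of variance, horizontal axis) and the second (21.9%, vertical axis), 1 point per array, from the 20834 probe sets tested. The 3 arrays of each of the 4 groups lie together and apart from the other groups.

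The first comparison asked what changed when brain NSCs differentiated. In differentiated brain cultures, transcripts of oligodendrocytes and astrocytes were higher than in proliferative ones, and so were interferon-induced genes, though none of these list calls held with an estimated correlation (adjusted p = 0.0536 for each glial list and 0.414 for interferon). Tril, a Toll-like receptor accessory protein found in astrocytes, rose from 7.16 ± 0.32 to 13.03 ± 0.02, which is 58.4-fold (adjusted p = 2.5e-10). Gfap, the intermediate filament of astrocytes, rose 5.58-fold to 14.31 ± 0.09 (adjusted p = 2.8e-05), and Aqp4, the astrocyte water channel, rose 27.7-fold (another probe set, dim in proliferative cultures, at least 3.31-fold). The falls with the largest size included Plau, the urokinase plasminogen activator, at 26.7-fold lower, and its receptor Plaur, at least 9.33-fold lower. Areg, a ligand of the EGF receptor, fell at least 16.3-fold, and Il11, a cytokine of the interleukin 6 family, at least 5.57-fold.

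Among glial lists in brain differentiation, 19 of 24 measured astrocyte genes rose and none fell (20 and 0 adjusted over the list alone), with a median change of 2.08 (camera adjusted p = 8.44e-10, and adjusted p = 0.0536 with an estimated correlation). Besides Aqp4, Acsbg1, an acyl-CoA synthetase, rose 21.9-fold and Sparcl1, a matrix protein secreted by astrocytes, 10.1-fold. Oligodendrocyte precursor genes rose in 12 of 13 cases with 0 falls (12 and 0 adjusted over the list alone). The oligodendrocyte precursor list had a median of 1.94 (camera adjusted p = 7.05e-08, and adjusted p = 0.0536 with an estimated correlation). Examples were Sox10, the transcription factor of the oligodendrocyte lineage, at 14.2-fold, Bcas1 at 13.6-fold (adjusted p = 1.2e-10), and Pcdh15, a protocadherin, at least 4.41-fold. Of 20 mature oligodendrocyte genes 17 rose and 0 fell (17 and 0 adjusted over the list alone). For the mature oligodendrocyte list the median was 3.08, and 2.0 with dim groups at the floor (camera adjusted p = 2.3e-09, and adjusted p = 0.0536 with an estimated correlation). Mag, a myelin-associated glycoprotein, rose 29.0-fold, and Ugt8, which makes the myelin lipid galactocerebroside, 29.9-fold. Aspa, the enzyme that splits N-acetylaspartate, rose at least 9.75-fold. Mbp, myelin basic protein, rose 22.6-fold (71.4-fold by another probe set), and 33.9-fold when brain proliferative replicate 2 was left out. Pdgfra, the receptor on oligodendrocyte precursors, rose 1.58-fold, and Olig2, a factor of the same lineage, was not called (log2 change 0.43, adjusted p = 0.58). Genes of ependymal cells and motile cilia rose in 6 of 15 cases with 0 falls (6 and 0 adjusted over the list alone), among them Foxj1, the master factor of motile cilia, at 3.53-fold and Dynlrb2, a dynein light chain, at 7.29-fold. The ependymal list had a median of 1.29 (camera adjusted p = 0.0272, and adjusted p = 0.3 with an estimated correlation).

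Interferon-response and antigen presentation genes rose in 26 of 27 cases in brain differentiation, with 0 falls (26 and 0 adjusted over the list alone). For the interferon list the median was 1.84 (camera adjusted p = 3.68e-10, and adjusted p = 0.414 with an estimated correlation). Ifit2 rose 21.9-fold, Rsad2, the antiviral protein viperin, 15.5-fold, Mx2 13.7-fold and Isg15, a ubiquitin-like protein, 12.4-fold. Markers of microglia and macrophages moved with them: 11 of 19 rose and 2 fell (12 and 2 adjusted over the list alone), with Fcer1g, an Fc receptor chain, at 6.10-fold and Aif1 at least 3.51-fold higher. The microglial list had a median of 1.12, and 0.36 with dim groups at the floor (camera adjusted p = 0.00965, and adjusted p = 0.501 with an estimated correlation).

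Neuronal genes were lower in differentiated brain cultures, where 18 of 32 fell, 4 rose and 10 were not called (22 down and 4 up adjusted over the list alone). For the neuronal list the median was -1.06 (camera adjusted p = 0.004, and adjusted p = 0.501 with an estimated correlation). Gad1, which makes the transmitter GABA, fell 6.31-fold, its paralogue Gad2 at least 8.98-fold, and Snap25, a protein of synaptic vesicle fusion, 6.70-fold. Dcx, a microtubule protein of young neurons, was not called (log2 change -0.54, adjusted p = 0.071) but was without brain proliferative replicate 3 (log2 change -0.84, adjusted p = 0.00346), after median centring (adjusted p = 0.0152) or with a pseudocount of 64 (adjusted p = 0.0478). Tubb3, neuronal tubulin, fell 1.64-fold with its call lost without brain proliferative replicate 1 (log2 change -0.46, adjusted p = 0.0722). Neural stem and progenitor genes went both ways, 10 up, 4 down and 8 not called of 22 (10 and 5 adjusted over the list alone; camera adjusted p = 0.329), with a median of 0.13 whose sign depended on the scaling. Sox2, a factor that maintains NSCs, rose 1.54-fold (another probe set at log2 0.32 was not called) and Nes, the filament nestin, fell 1.77-fold, while Hmga2, a chromatin protein of fetal progenitors, fell at least 4.46-fold.

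DNA replication genes fell in 15 of 26 cases with 0 rises (17 and 0 adjusted over the list alone). The replication list had a median of -0.74 (camera adjusted p = 0.0029, and adjusted p = 0.605 with an estimated correlation). Hells, a helicase of DNA methylation, fell 2.84-fold, Cdt1, which licenses replication origins, 2.51-fold, and Mcm6, a part of the replicative helicase, 2.17-fold. Of the mitosis genes, 8 of 27 rose, 0 fell and 19 were not called (7 and 0 adjusted over the list alone). For the mitosis list the median was 0.36 (camera adjusted p = 0.0708, and 0.0055 without brain proliferative replicate 3). Ccnb2, cyclin B2, rose 2.61-fold and Birc5, survivin, 1.93-fold, and Mki67, a protein of cycling cells, had a log2 change of 0.47 that was not called (adjusted p = 0.074, and 0.0419 without the same array).

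Cholesterol biosynthesis genes fell in 16 of 21 cases with 0 rises (16 and 0 adjusted over the list alone), among them Ebp at 2.75-fold, Mvd at 2.37-fold and Fdps, farnesyl diphosphate synthase, at 2.32-fold lower. The cholesterol list had a median of -0.58 (camera adjusted p = 0.00015, and adjusted p = 0.491 with an estimated correlation). Immediate early genes, which respond to growth factors within minutes, fell in 13 of 21 cases and rose in 2 (14 and 2 adjusted over the list alone). For the immediate early list the median was -1.11 (camera adjusted p = 0.00042, and adjusted p = 0.0628 with an estimated correlation). Fosl1 fell 12.1-fold, Egr1 4.33-fold and Egr2 4.01-fold, and another probe set of Egr2, dim in both groups, was not called. The unfolded protein and amino acid stress list had 16 falls and 4 rises among 25 (16 and 4 adjusted over the list alone), with Mthfd2, a mitochondrial folate enzyme, 3.21-fold lower and Slc7a11, the cystine transporter, 5.09-fold higher. The stress response list had a median of -0.42 (camera adjusted p = 0.0293, and adjusted p = 0.369 with an estimated correlation). Bmp4, a growth factor of glial differentiation, rose at least 21.0-fold while Bmp2 fell 13.1-fold, and the BMP list, with 6 rises and 4 falls among 23 (6 and 4 adjusted over the list alone), was not called (median -0.04, and 0.07 with dim groups at the floor, camera adjusted p = 0.692).

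Across all probe sets, 4942 rose and 4821 fell in brain differentiation, 2491 and 1518 of them by at least 2-fold. Leaving out 1 array at a time the counts ran from 4165 to 4572 and from 4109 to 4566. Rises made up 50.6% of calls, and 38.2% after median centring. Control signals moved with the state here. The 5S rRNA control was 9.50, 11.02 and 9.61 on the proliferative and 7.85, 8.19 and 8.05 on the differentiated brain arrays. For Gapdh the 3' minus 5' signal, a sign of RNA quality, was 0.13, 0.09 and 0.08 on the former and -0.13, 0.07 and -0.02 on the latter.

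**Figure D2:**
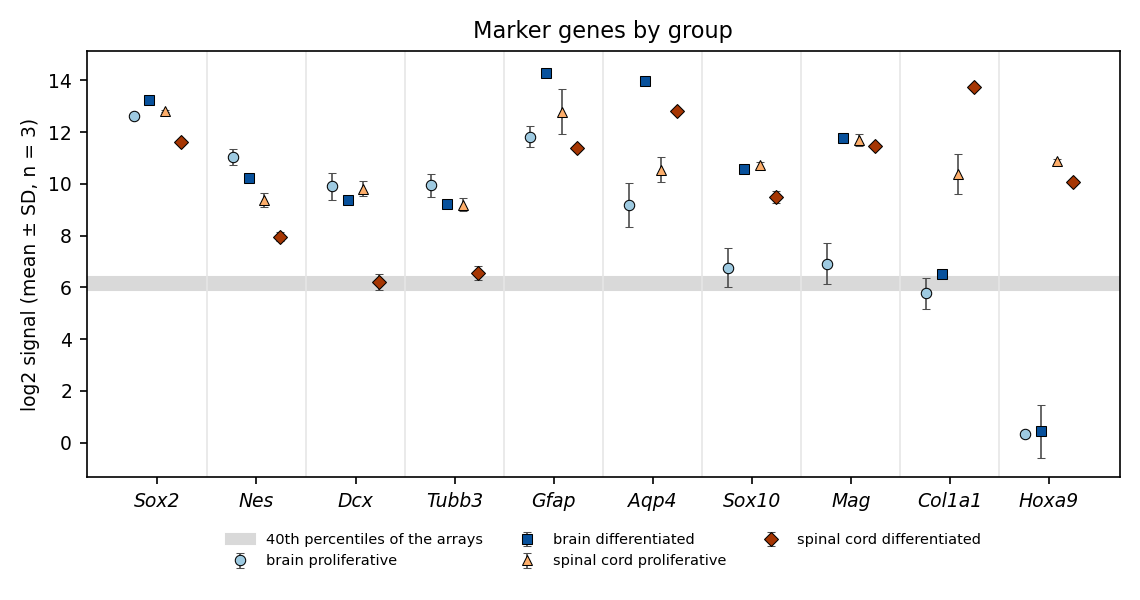
Log2 signal (vertical axis, mean ± SD, n = 3) of 10 marker genes in the 4 groups, with the range of the arrays' 40th percentiles (5.91 to 6.41) as a grey band. Gfap lies at 14.31 in differentiated brain and 11.40 in differentiated spinal cord cultures, Col1a1 at 6.52 and 13.74, and Hoxa9 is below the band in both brain groups.

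The same question was asked of spinal cord NSCs. Spinal cord cultures responded to differentiation with a fall of neuronal, oligodendrocyte precursor and stem cell genes and a rise of connective tissue genes. With an estimated correlation these list calls were lost (adjusted p = 0.204 for neurons and 0.174 for the others). Dcx fell 12.2-fold, from 9.81 ± 0.29 to 6.20 ± 0.29 (adjusted p = 7.7e-08), and Sox11, a factor of immature neurons and progenitors, 36.1-fold. Scg2, a secretory granule protein of neuroendocrine cells, fell 41.6-fold (adjusted p = 3.4e-12). The largest rises included Hp, haptoglobin, at least 64.2-fold, Mme, the cell surface peptidase neprilysin, at least 38.7-fold, and Cdh1, the epithelial cadherin, at least 16.6-fold. Ogn, the matrix proteoglycan osteoglycin, rose 91.0-fold, and Il11 fell at least 13.1-fold.

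None of 32 neuronal genes rose with differentiation in spinal cord cultures, while 19 fell and 13 were not called (0 and 22 adjusted over the list alone). For the neuronal list the median was -1.74 (camera adjusted p = 1.08e-08, and adjusted p = 0.204 with an estimated correlation). Npy, a neuropeptide, fell 17.0-fold, Stmn3, a tubulin-binding protein, 14.5-fold, Elavl4, an RNA-binding protein of neurons, 12.3-fold, and Tubb3 6.21-fold. Stem and progenitor genes fell in 14 of 22 cases and rose in 2 (14 and 2 adjusted over the list alone), with Nes 2.72-fold and Sox2 2.27-fold lower. The progenitor list had a median of -1.16 (camera adjusted p = 0.00067, and adjusted p = 0.174 with an estimated correlation). Of 13 oligodendrocyte precursor genes 10 fell and 1 rose (11 and 1 adjusted over the list alone). For the oligodendrocyte precursor list the median was -2.13 (camera adjusted p = 1.61e-05, and adjusted p = 0.174 with an estimated correlation). Cspg4, the NG2 proteoglycan, fell 10.8-fold, Cspg5 5.73-fold, Olig2 at least 2.41-fold and Pcdh15 at least 7.45-fold, whereas Pdgfra rose 1.65-fold. Mature oligodendrocyte genes had 3 rises and 6 falls among 20 (3 and 6 adjusted over the list alone; median -0.22, camera adjusted p = 0.688), and Mbp was 14.19 ± 0.03 before and 14.38 ± 0.12 after (adjusted p = 0.69). Astrocyte genes rose in 8 and fell in 7 of 24 cases (8 and 7 adjusted over the list alone; median 0.26, and -0.07 with dim groups at the floor, camera adjusted p = 0.603): Gja1, connexin 43, rose 4.36-fold (23.4-fold by another probe set) and Aqp4 4.82-fold (1.92-fold by another), while Gfap fell 2.64-fold to 11.40 ± 0.11.

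Genes of fibroblasts, meninges and mural cells rose in 15 of 21 cases with 0 falls in spinal cord differentiation (15 and 1 adjusted over the list alone). The fibroblast list had a median of 1.80 (camera adjusted p = 4.92e-06, and adjusted p = 0.174 with an estimated correlation). Col1a1, the main chain of type I collagen, rose 10.3-fold to 13.74 ± 0.07, and Lox, which crosslinks collagen, 14.3-fold to 13.86 ± 0.09. Interferon genes rose in 24 of 27 cases with 0 falls (26 and 0 adjusted over the list alone), led by Isg15 at 8.26-fold, Psmb8, an immunoproteasome subunit, at 5.03-fold and Irf7 at 3.96-fold. For the interferon list the median was 1.48 (camera adjusted p = 1.08e-08, and adjusted p = 0.486 with an estimated correlation). Of 19 microglial markers 1 rose and 7 fell in the same cultures (1 and 7 adjusted over the list alone), with the complement chain C1qa 7.99-fold lower. The microglial list had a median of -0.13 (camera adjusted p = 0.478).

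Immediate early genes fell in 11 of 21 cases with 0 rises (11 and 0 adjusted over the list alone), with Egr2 5.12-fold, Fos 3.96-fold and Nr4a1 3.10-fold lower. Another probe set of Egr2, dim in both groups, was not called (log2 change -0.14). For the immediate early list the median was -0.51 (camera adjusted p = 0.00777, and adjusted p = 0.174 with an estimated correlation). Mitosis genes fell in 8 of 27 cases with 0 rises (7 and 0 adjusted over the list alone), among them Pbk at 2.33-fold, Top2a, topoisomerase II, at 1.94-fold and Aurka, a mitotic kinase, at 1.91-fold. The mitosis list had a median of -0.44 (camera adjusted p = 0.0201, and adjusted p = 0.845 with an estimated correlation). This list's call rested on 1 array, since without spinal cord proliferative replicate 1 the median was -0.16 and the adjusted p = 0.425. DNA replication genes had 2 rises and 4 falls (2 and 4 adjusted over the list alone). For the replication list the median was -0.22 (camera adjusted p = 0.559, and 0.0463 without spinal cord proliferative replicate 2). Schwann cell genes had 1 rise and 6 falls among 11 (1 and 7 adjusted over the list alone). The Schwann cell list had a median of -1.17 (camera adjusted p = 0.0803, and 0.045 without the same array).

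The counts for spinal cord differentiation were 3806 probe sets up and 4590 down, of which 1606 and 2073 changed by at least 2-fold. Leaving out 1 array at a time they ran from 3098 to 3943 and from 3808 to 4472, and were highest without spinal cord proliferative replicate 1. Rises were 45.3% of calls, and 52.3% after median centring.

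**Figure D3:**
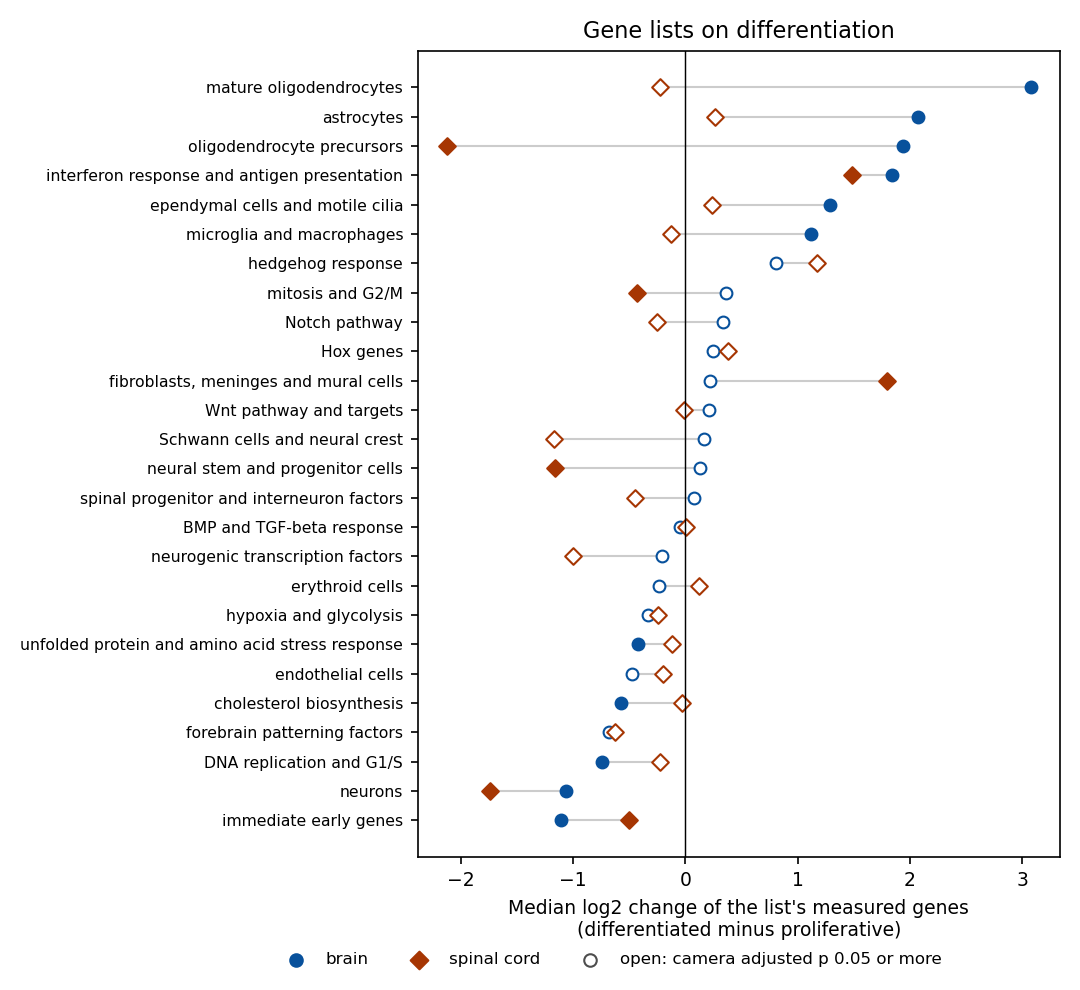
Median log2 change on differentiation (horizontal axis) of the measured genes of each of the 26 lists, for brain (circles) and spinal cord (diamonds) cultures. Filled symbols have a camera adjusted p under 0.05 with the preset correlation, and no such call held with an estimated correlation. Oligodendrocyte precursor genes lie at 1.94 in brain and -2.13 in spinal cord, and interferon genes at 1.84 and 1.48, while the direction of uncalled medians near 0 depended on the scaling for stem cell and spinal progenitor genes in brain and for Wnt and cholesterol genes in spinal cord.

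To see how NSCs of both tissues differ while dividing, their proliferative cultures were compared. Proliferative spinal cord cultures differed from proliferative brain cultures in the Hox genes, which set position along the body axis: 18 of 18 measured were higher in spinal cord (18 and 0 adjusted over the list alone). Of these, 17 were dim in both brain groups and so passed the filter only through spinal cord arrays. A count in 1 direction was therefore likely beforehand. On the deposited values, which include those of the dim brain groups, the median of the Hox list was 5.67 (camera adjusted p = 1e-13). With dim groups at the floor it was 2.69, which was not tested. Hoxa5 was at least 38.5-fold, Hoxa9 at least 27.1-fold and Hoxc8 at least 7.27-fold higher, and these genes were dim in brain cultures. Lower in spinal cord were Emx2, a factor of the developing cerebral cortex, at least 15.9-fold, Pnoc, the precursor of nociceptin, at least 37.2-fold, and Pax6, a factor of neural progenitors, 5.62-fold. Forebrain patterning factors as a group were lower in 8 of 13 cases and higher in 2 (8 and 2 adjusted over the list alone). The forebrain list had a median of -1.51, and -0.75 with dim groups at the floor (camera adjusted p = 0.0396, and adjusted p = 0.412 with an estimated correlation). That call was lost without brain proliferative replicate 1 (adjusted p = 0.0503) or 2 (adjusted p = 0.087). Spinal progenitor factors were higher in 5 of 7 cases with 0 lower (6 and 0 adjusted over the list alone), including Irx3 at 6.61-fold (2.75-fold by another probe set) and Nkx6-2 at least 5.38-fold. For the spinal factor list the median was 1.96 (camera adjusted p = 0.00161, and adjusted p = 0.119 with an estimated correlation).

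Oligodendrocyte genes were higher in proliferative spinal cord than in proliferative brain cultures. Of 20 mature oligodendrocyte genes 17 were higher than in brain and 0 lower (19 and 0 adjusted over the list alone), with Mag 27.6-fold and Mobp, a myelin protein, at least 11.4-fold higher. The mature oligodendrocyte list had a median of 3.62, and 2.78 with dim groups at the floor (camera adjusted p = 1e-13). Precursor genes were higher in 11 of 13 cases with 0 lower (11 and 0 adjusted over the list alone), such as Sox10 at 15.9-fold, Cspg4 at 12.8-fold and Pdgfra at 3.54-fold. For the oligodendrocyte precursor list the median was 2.12 (camera adjusted p = 4.3e-09). Mbp was 19.3-fold higher, 6.52-fold and 56.0-fold by other probe sets, and 29.0-fold without brain proliferative replicate 2. Markers of other cell types were higher too. All 19 microglia and macrophage genes were higher (19 and 0 adjusted over the list alone), such as Ctss, a lysosomal protease, at 20.7-fold and Cd53, a leukocyte membrane protein, at least 9.70-fold. Of these 19 genes, 10 had a dim group in this contrast. The microglial list had a median of 3.31, and 2.30 with dim groups at the floor (camera adjusted p = 6.88e-12, and adjusted p = 0.085 with an estimated correlation). Fibroblast, meningeal and mural genes were higher in 13 of 21 cases and lower in 2 (14 and 2 adjusted over the list alone), with Dcn, the matrix proteoglycan decorin, 131-fold and Col3a1, a chain of type III collagen, 59.1-fold higher. For the fibroblast list the median was 1.35 (camera adjusted p = 1.99e-05, and adjusted p = 0.151 with an estimated correlation).

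Interferon genes were higher in 14 of 27 cases and lower in 1 (16 and 1 adjusted over the list alone), with Ifit2 at 7.80-fold, in the same cultures in which the microglial markers were higher. The interferon list had a median of 0.68 (camera adjusted p = 0.000579, and adjusted p = 0.704 with an estimated correlation). Mitosis genes were higher in 20 of 27 cases with 0 lower (22 and 0 adjusted over the list alone), for example Ccnb2 at 2.73-fold, Top2a at 2.43-fold and Mki67 at 2.17-fold. For the mitosis list the median was 0.78 (camera adjusted p = 1.52e-06, and adjusted p = 0.584 with an estimated correlation). DNA replication genes had 0 higher and 1 lower of 26 (0 and 0 adjusted over the list alone; median -0.11, camera adjusted p = 0.86), and without spinal cord proliferative replicate 1 their median was -0.47 (adjusted p = 0.00443). Lower in spinal cord were cholesterol biosynthesis genes, 18 of 21 with 0 higher (18 and 0 adjusted over the list alone; median -0.55, camera adjusted p = 1.31e-05, and adjusted p = 0.412 with an estimated correlation), among them Tm7sf2 at 2.33-fold and Fdps at 2.03-fold, and ependymal and cilia genes, 5 of 15 with 0 higher (4 and 0 adjusted over the list alone). The ependymal list had a median of -0.88, and -0.38 with dim groups at the floor (camera adjusted p = 0.0295, and adjusted p = 0.223 with an estimated correlation). The ependymal call was lost without brain proliferative replicate 1 (adjusted p = 0.0881). Neuronal genes went both ways, 5 higher and 12 lower of 32 (6 and 12 adjusted over the list alone; median -0.33, camera adjusted p = 0.271, and 0.0226 without brain proliferative replicate 3), with Gad1 4.19-fold lower (another probe set, dim in spinal cord, was not called at a log2 difference of -1.31), and Dcx was not called (log2 difference -0.10, adjusted p = 0.78). Nes was 3.13-fold lower in spinal cord, and Sox2 was 12.81 ± 0.04 against 12.62 ± 0.08 (adjusted p = 0.068, and 0.00732 after quantile normalization). The 2 other probe sets of Sox2 had the opposite sign, at log2 differences of -0.31 and -0.07, and were not called.

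Between proliferative cultures 4033 probe sets were higher and 3844 lower in spinal cord, 2207 and 889 of them by at least 2-fold. The share of higher calls was 51.2%, and 31.7% after median centring. With 1 array left out the counts ran from 3365 to 4300 and from 3054 to 4348, and were highest without spinal cord proliferative replicate 1. The 5S rRNA control moved with the tissue, at 8.65, 9.38 and 9.17 on the proliferative spinal cord arrays and 9.50, 11.02 and 9.61 on the proliferative brain arrays.

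The tissues were next compared in the differentiated state. Between differentiated cultures genes of connective tissue were among the largest differences. Dcn was 14.24 ± 0.13 in spinal cord and dim in brain cultures, at least 245-fold higher (adjusted p = 1.2e-08), and Lum, the proteoglycan lumican, was at least 156-fold and Lox at least 189-fold higher. Pla2g2a, a secreted phospholipase, and Lbp, a protein that binds bacterial lipopolysaccharide, were each at least 154-fold higher. Col1a1 was 149-fold higher. In the other direction Lhx2, a factor of forebrain progenitors, was at least 44.2-fold lower in spinal cord, and Rlbp1, a retinaldehyde-binding protein of glia, 48.9-fold lower. Gfap was 7.53-fold, Dcx 8.95-fold and Sox2 3.06-fold lower.

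The fibroblast, meningeal and mural list was higher in 16 of 21 cases with 0 lower in differentiated spinal cord cultures (16 and 0 adjusted over the list alone). For the fibroblast list the median was 4.73, and 3.23 with dim groups at the floor (camera adjusted p = 9.94e-10, and a median of 3.96 without brain differentiated replicate 3). Hox genes were higher in 18 of 18 cases (18 and 0 adjusted over the list alone), with Hoxa5 at least 50.9-fold and Hoxc8 at least 10.8-fold. As 17 of the 18 passed the filter only through spinal cord arrays, a count in 1 direction was likely beforehand here too. The Hox list had a median of 5.37 on the deposited values, which include those of the dim brain groups (camera adjusted p = 3.97e-12). With dim groups at the floor it was 3.04, which was not tested. Spinal progenitor factors had 2 higher and 0 lower of 7 (2 and 0 adjusted over the list alone; median 0.69, and 0.15 with dim groups at the floor, camera adjusted p = 0.175), with Irx3 16.8-fold higher (at least 4.61-fold by another probe set), and forebrain patterning factors 3 higher and 7 lower of 13 (3 and 9 adjusted over the list alone). For the forebrain list the median was -1.89, and -0.54 with dim groups at the floor (camera adjusted p = 0.124). Microglia and macrophage genes were higher in 14 of 19 cases with 0 lower (14 and 0 adjusted over the list alone), for instance Cd14, a receptor for lipopolysaccharide, at 5.93-fold. The microglial list had a median of 1.35 (camera adjusted p = 6.31e-05, and adjusted p = 0.22 with an estimated correlation). The unfolded protein and amino acid stress list had 15 higher and 3 lower of 25 (15 and 3 adjusted over the list alone). For the stress response list the median was 0.51 (camera adjusted p = 0.00383, and adjusted p = 0.133 with an estimated correlation). Nupr1, a stress-induced chromatin protein, was 32.2-fold higher, whereas the serine synthesis enzymes Phgdh and Psat1 were 2.63-fold and 2.52-fold lower.

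Stem cell, astrocyte, neuronal and oligodendrocyte precursor genes were lower in differentiated spinal cord than in differentiated brain cultures, and of these list calls only that of stem cells held with an estimated correlation (adjusted p = 0.0151). Stem and progenitor genes were lower in 16 of 22 cases and higher in 1 (17 and 1 adjusted over the list alone), with Sox11 12.3-fold, Pax6 10.2-fold and Nes 4.81-fold lower. The progenitor list had a median of -1.46 (camera adjusted p = 5.43e-08). Astrocyte genes were lower in 20 of 24 cases and higher in 1 (20 and 2 adjusted over the list alone), including Acsbg1 at 13.7-fold. For the astrocyte list the median was -2.11, and -1.50 with dim groups at the floor (camera adjusted p = 7.73e-08, and adjusted p = 0.0532 with an estimated correlation). Neuronal genes had 20 lower and 3 higher of 32 (20 and 4 adjusted over the list alone), with Stmn3 9.22-fold and Tubb3 6.32-fold lower. The neuronal list had a median of -1.57, and -0.90 with dim groups at the floor (camera adjusted p = 9.08e-06, and adjusted p = 0.22 with an estimated correlation). Oligodendrocyte precursor genes were lower in 11 of 13 cases and higher in 2 (11 and 2 adjusted over the list alone), such as Cspg5 at 13.4-fold and Ptprz1 at 5.74-fold (10.2-fold by another probe set), and Pdgfra was one of the 2, at 3.69-fold higher. For the oligodendrocyte precursor list the median was -1.86 (camera adjusted p = 0.000152, and adjusted p = 0.118 with an estimated correlation). Mature oligodendrocyte genes had 5 higher and 4 lower of 20 (5 and 4 adjusted over the list alone; median 0.15, camera adjusted p = 0.703), and Mbp differed by -0.03 (adjusted p = 0.95). Ependymal and cilia genes were lower in 13 of 15 cases with 0 higher (13 and 0 adjusted over the list alone), for example Dynlrb2 at 5.72-fold. The ependymal list had a median of -1.86 (camera adjusted p = 4.68e-05). DNA replication genes had 4 higher and 0 lower of 26 (3 and 0 adjusted over the list alone; median 0.39, camera adjusted p = 0.0589) and mitosis genes 3 higher and 1 lower of 27 (1 and 0 adjusted over the list alone; median 0.07, camera adjusted p = 0.703), and Mki67 differed by -0.04 (adjusted p = 0.89).

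The tissue contrast in differentiated cultures gave 3856 probe sets higher and 4761 lower in spinal cord, with 1875 and 2231 at 2-fold or more. Leaving out 1 array gave 3247 to 3466 and 3903 to 4365. The 3' minus 5' signal of Actb, a sign of RNA quality, moved with the tissue here: it was 0.99, 1.01 and 0.99 on the differentiated spinal cord arrays and 0.81, 0.73 and 0.81 on the differentiated brain arrays.

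The responses to differentiation were then set against each other, as the change in spinal cord minus the change in brain. Oligodendrocyte, astrocyte and stem cell genes had the more negative response in spinal cord, and fibroblast genes the more positive one, but no such list call held with an estimated correlation (smallest adjusted p = 0.0559). For mature oligodendrocyte genes the tissues differed mainly before differentiation. Their median was 3.62 higher in spinal cord between proliferative cultures (2.78 with dim groups at the floor) and 0.15 higher between differentiated ones. Sox10 had a log2 difference of -5.08 (adjusted p = 3.3e-07), Mag -5.11, Ugt8 -5.48, Gfap -3.88 (adjusted p = 1.5e-05), S100b, a calcium-binding protein of glia, -4.60, and Rlbp1 -8.34. On the positive side, Foxp2, a transcription factor, had a difference of at least 5.14 (adjusted p = 9.7e-07) and Tspan8, a tetraspanin of epithelial cells, one of at least 4.16.

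**Figure D4:**
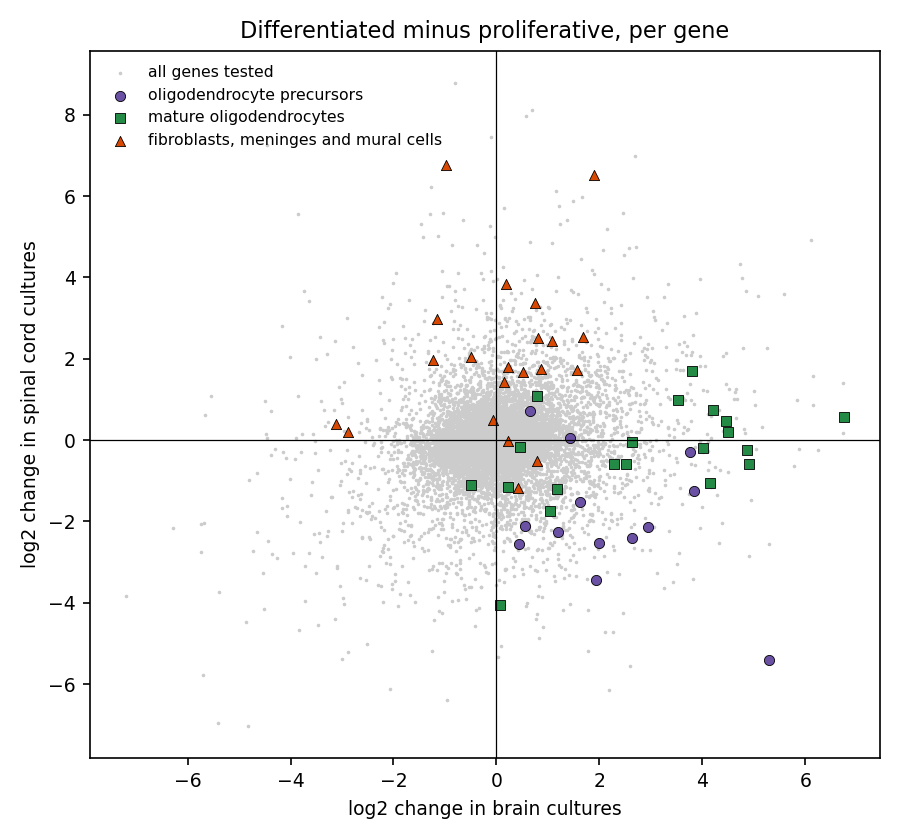
Log2 change on differentiation in brain cultures (horizontal axis) against spinal cord cultures (vertical axis) for each of the 11218 genes tested (grey), with the genes of 3 lists coloured. Across all genes r was 0.16, oligodendrocyte precursor genes lie mostly to the right of and below 0, and fibroblast genes mostly above 0.

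By list, the response difference was negative for oligodendrocyte precursors in 12 of 13 genes with 0 positive (12 and 0 adjusted over the list alone; median -4.06, camera adjusted p = 5.08e-10, and adjusted p = 0.0559 with an estimated correlation) and for mature oligodendrocytes in 17 of 20 with 0 positive (18 and 0 adjusted over the list alone). For the mature oligodendrocyte list the median was -2.98 (camera adjusted p = 1.88e-09, and adjusted p = 0.0613 with an estimated correlation). It was negative for 14 of 24 astrocyte genes and positive for 1 (17 and 1 adjusted over the list alone; median -1.95, camera adjusted p = 4.08e-06, and adjusted p = 0.12 with an estimated correlation), and for 12 of 22 stem and progenitor genes and positive for 1 (13 and 1 adjusted over the list alone). The progenitor list had a median of -0.85 (camera adjusted p = 0.000629, and adjusted p = 0.0613 with an estimated correlation). Microglia and macrophage genes had 11 negative and 0 positive differences among 19 (12 and 0 adjusted over the list alone; median -1.64, and -0.75 with dim groups at the floor, camera adjusted p = 0.00317, and adjusted p = 0.474 with an estimated correlation), with C1qa at -3.90. Neuronal genes had 14 negative and 5 positive (14 and 5 adjusted over the list alone). For the neuronal list the median was -0.74, and -0.16 with dim groups at the floor (camera adjusted p = 0.0158, and adjusted p = 0.553 with an estimated correlation). This call was lost without brain proliferative replicate 3 (median -0.49, adjusted p = 0.0751). Elavl4 stood at -3.32, Dcx at -3.07 and Tubb3 at -1.92. Mitosis genes had 13 negative and 0 positive (14 and 0 adjusted over the list alone; median -0.78, camera adjusted p = 0.00169, and adjusted p = 0.597 with an estimated correlation), including Top2a at -1.43 and Mki67 at -1.16. DNA replication genes had 6 positive and 0 negative (5 and 0 adjusted over the list alone; median 0.36) and as a list were called without spinal cord proliferative replicate 1 (camera adjusted p = 0.0934 with all arrays; 0.69 and 0.00013 without it).

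Positive response differences were found for 13 of 21 fibroblast, meningeal and mural genes, with 1 negative (14 and 2 adjusted over the list alone; median 1.58, camera adjusted p = 0.000905, and adjusted p = 0.31 with an estimated correlation), for example Lox at 3.08 or more. Cholesterol biosynthesis genes had 12 positive and 0 negative of 21 (12 and 0 adjusted over the list alone; median 0.55, camera adjusted p = 0.00171, and adjusted p = 0.533 with an estimated correlation), led by Ebp at 2.57. In the unfolded protein and amino acid stress list 12 of 25 were positive and 2 negative (13 and 2 adjusted over the list alone). The stress response list had a median of 0.55 (camera adjusted p = 0.0463, and adjusted p = 0.37 with an estimated correlation). Leaving out any of 6 single arrays ended that call, with adjusted p = 0.0741 without brain proliferative replicate 1, 0.0634 without replicate 3, 0.0523 and 0.0635 without brain differentiated replicates 1 and 2, 0.0697 without spinal cord proliferative replicate 3 and 0.0568 without spinal cord differentiated replicate 1. Interferon genes had 2 positive and 8 negative of 27 (2 and 10 adjusted over the list alone), and the list was not called (median -0.59, camera adjusted p = 0.0934), but was called without brain proliferative replicate 2 (adjusted p = 0.0239) or spinal cord proliferative replicate 1 (adjusted p = 0.000962). Pdgfra (0.06, adjusted p = 0.88) and Nes (-0.62, adjusted p = 0.055) were not called. Pdgfra was without brain proliferative replicate 1 (0.37, adjusted p = 0.0272). Nes was called after quantile normalization (adjusted p = 0.041) and when any of 4 single arrays was left out, most clearly brain proliferative replicate 3 (-0.79, adjusted p = 0.013).

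In all, 3916 probe sets had a more positive and 4518 a more negative response in spinal cord, with positive calls at 46.4%, and 61.3% after median centring. With 1 array left out the counts ran from 3457 to 4361 and from 3989 to 4818, and were highest without spinal cord proliferative replicate 1.

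Of 11218 genes, 815 rose in both tissues on differentiation against 564 for independent lists (Fisher's exact test across genes, p = 5.4e-40), and 931 fell in both against 723 (p = 1.5e-24). Genes up in brain and down in spinal cord numbered 612, against 612 for independent lists (Fisher's exact p = 1), and 495 were down in brain and up in spinal cord, against 666 (p = 2.13e-19). Across genes, which are not independent replicates, Pearson's r of the changes was 0.16 and Spearman's rho 0.15. Of the tissue differences, 816 genes were higher in spinal cord in both states (529 for independent lists, p = 2.8e-53) and 592 lower in both (572, p = 0.28), with r = 0.38 and rho = 0.10. Another 660 were higher in the proliferative and lower in the differentiated contrast (531, Fisher's exact p = 2.56e-12), and 536 the reverse (569, p = 0.0742). After median centring these were 437 (341 for independent lists, Fisher's exact p = 8.86e-10) and 692 (839, p = 6.66e-13), and with array weights 831 (726, p = 2.46e-07) and 807 (830, p = 0.273). The contrasts set against each other here share no array, but they share the same estimate of each probe set's spread. Genes with a small spread are called more easily in both, which can raise an overlap above that of independent lists. The Fisher tests also take genes as independent.

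**Figure D5:**
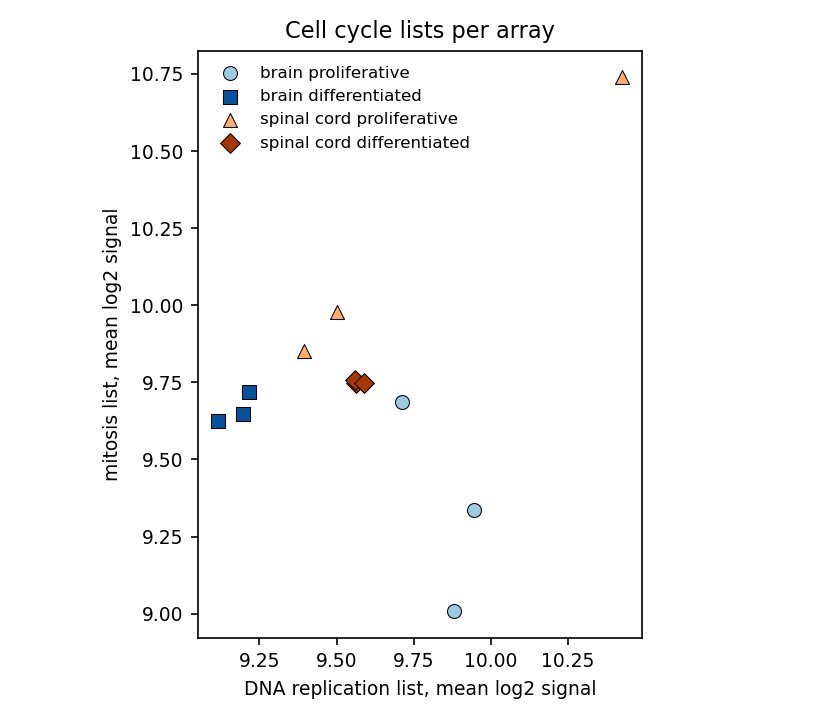
Mean log2 signal of the mitosis list (vertical axis) against that of the DNA replication list (horizontal axis), 1 point per array in 4 groups of 3. Differentiated brain arrays lie at lower replication values than proliferative brain arrays, and spinal cord proliferative replicate 1 lies apart at 10.4 and 10.7.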

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

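In this part the splits of 6 arrays were planned, and the reassignment for the difference of responses and the tests of the connective tissue genes were chosen after the results were seen. The results here were picked out because the responses to differentiation differed between brain and spinal cord, by the limma test of that difference for probe sets and genes and by camera for lists. Values are log2 changes in spinal cord minus those in brain.

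The difference was called for 3916 probe sets with a more positive response in spinal cord and 4518 with a more negative one. Positive calls were 46.4%, 50.5% after quantile normalization and 61.3% after median centring, so the majority direction depended on the scaling. Among genes called in both tissues in opposite directions, 612 rose in brain and fell in spinal cord, and 495 fell in brain and rose in spinal cord. Independent lists would give 612 and 666, so opposite directions were not more frequent than that. By list, medians were -4.06 for oligodendrocyte precursors, -2.98 for mature oligodendrocytes, -1.95 for astrocytes, -1.64 for microglia and macrophages (-0.75 with dim groups at the floor), -0.85 for neural stem and progenitor cells, -0.78 for mitosis and -0.74 for neurons (-0.16 with dim groups at the floor). The mature oligodendrocyte median came with a list already 3.62 higher in proliferative spinal cord cultures (2.78 with dim groups at the floor) and 0.15 higher in differentiated ones. Positive medians were 1.58 for fibroblast, meningeal and mural genes and 0.55 each for cholesterol biosynthesis and the unfolded protein and amino acid stress response. None of the list calls for the difference of responses held with an estimated correlation, where the smallest adjusted p among them was 0.0559.

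Of single genes with a negative difference, Rlbp1 stood at -8.34. Against dim groups only bounds are given, which have no order: -5.68 or lower for B3galt5, a galactosyltransferase, -5.04 or lower for Pcdh15, -4.84 or lower for Igsf21 and -4.45 or lower for Ncam2. On the positive side the difference was at least 5.14 for Foxp2 and at least 4.16 for Tspan8, which was at least 4.81 without brain proliferative replicate 2. Cdh1, Hp and Slc6a13, a GABA transporter, were called too, but were dim in both brain groups and so have no size here. Of the genes named in every comparison, Mbp stood at -4.30 (-3.48 and -6.31 by other probe sets, -4.89 without brain proliferative replicate 2), Gfap at -3.88, Dcx at -3.07, Olig2 at -1.70 or lower (-1.10 or lower without brain proliferative replicate 3), Tubb3 at -1.92, Sox2 at -1.80 and Mki67 at -1.16.

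For the difference of responses, the deviations of the arrays from a model with equal responses were reassigned within each state, in 100 of 200 possible ways. Only 1 of the 100, the real one with 8434 called probe sets, reached that count, and the highest other had 909. Other reassignments mix arrays of groups that lie far apart, which widens the spread, so fewer calls were likely beforehand. As the arrays of a group may be technical repeats, a difference between single cultures or batches is not excluded. For each contrast of 2 groups there are 10 splits of the 6 arrays, too few for a share under 0.05, and 1 split, the real one, reached the real count. Fitted on those 6 arrays alone, the real counts were 10070 for brain differentiation, 7483 for spinal cord differentiation, 6152 between proliferative and 10073 between differentiated tissues, and the highest other was 0 in each.

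Connective tissue genes were higher in differentiated spinal cord than in differentiated brain cultures and rose in spinal cord differentiation, the latter with a list adjusted p = 0.174 with an estimated correlation. Array scaling of the size that quantile normalization removes was argued against as the only source. Over all probe sets that step shifted the change in spinal cord by 0.05, and the median rise of the fibroblast list was then 1.80. With so small a shift the rise was bound to stay, so scaling that this step leaves in place was not tested. A smaller share of neural RNA with an unchanged number of other cells would move the microglial list alike, but the fibroblast list rose by 1.93 more (interval 1.38 to 3.49 by a bootstrap that takes genes as independent), and on the arrays the mean of the fibroblast list minus that of the microglial list went from 0.46 ± 0.98 to 3.12 ± 0.07. That comparison takes the microglia as unchanged, while 7 of 19 microglial genes fell and 1 rose in spinal cord differentiation. It therefore cannot exclude a smaller share of neural RNA together with fewer microglia. A candidate source that stays open is fibroblast or meningeal cells in the spinal cord cultures: 10 of 10 abundant fibroblast transcripts, 3 of them in the fixed list, were called higher in differentiated spinal cord than in differentiated brain cultures, with Col3a1 at 14.7, Sparc at 14.3 and Col1a2 at 14.1 in the former. Of the same 10, 9 were already higher between proliferative cultures, with a median of 4.15, against 4.25 between differentiated ones. A more positive response in spinal cord was called for 4 of them. These genes are of the kind that showed the pattern and neural cells can transcribe some of them, as Sparc was at 13.4 in differentiated brain cultures, so such cells and a change of state in the spinal cord cells themselves cannot be told apart.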

How the results depend on the processing

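Alternatives added after seeing the data were the counts without calls dim in both groups, the lists without members dim in both groups, the lists without each array in turn and the list medians with dim groups at the floor; all others were planned. Of the values of counts, overlaps and numbers of called lists under the alternatives, 732 stayed within the bounds set and 41 moved beyond them. For named genes 7261 values kept direction and side of the threshold, 241 lost the call, 14 gained it, 4 moved and 1 reversed, and for lists 1586 kept both, 57 lost and 54 gained the call, 17 medians moved and 2 reversed.

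With the filter at the 60th percentile, which tests fewer probe sets, counts at 2-fold or more, higher and lower, were 1286 and 871 for brain differentiation, 815 and 996 for spinal cord differentiation, 1008 and 476 between proliferative tissues (2588 higher at any size), 773 and 1081 between differentiated tissues, and 1135 and 1741 for the difference of responses. Genes higher in both tissue contrasts were then 470, and Pearson's r was 0.194 for the differentiation responses and 0.27 for the tissue differences. For the next alternatives the cause was not tested. With a pseudocount of 64, probe sets at least 2-fold lower were 1365 in spinal cord differentiation and 1484 between differentiated tissues. Median centring gave 6214 probe sets lower between proliferative tissues, 1503 of them by 2-fold, 3956 genes lower, 2868 at least 2-fold higher for the difference of responses, and 437 genes higher in the proliferative and lower in the differentiated tissue contrast. Array weights gave 807 genes for the reverse order and r = 0.137 for the differentiation responses. Without a filter r was 0.135 and 0.319, and with pseudocounts of 16 and 64 the tissue r was 0.341 and 0.301. Leaving out 1 array at a time, r ran from 0.125 to 0.188 for the differentiation responses and from 0.364 to 0.395 for the tissue differences.

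Lists called were 11, 7, 11, 9 and 10 in the 5 contrasts in the order reported, 0, 0, 3, 4 and 0 with an estimated correlation, and 20, 13, 17, 19 and 17 with fry, which does not compare a list with other genes. Between proliferative tissues fry reversed the direction given by camera for neurogenic transcription factors (median -0.31) and hypoxia (median -0.021). For the gene Slc1a3 in that contrast 1 other probe set had the opposite direction (1.98, against -1.71), and the third agreed (-2.09). The causes were not tested. With the replicate number as a block the counts higher and lower were 4768 and 4647, 3639 and 4332, 3888 and 3643, 3682 and 4514, and 3734 and 4338. The pairing check found 0 of 18 same-numbered pairs over r = 0.1 (-0.12 to 0.05) and 0 of 12 arrays closest to their own number. No effect shared by same-numbered arrays was seen, which cannot show that they came from different animals, cultures or batches. Signal over background limits the dim genes, whose folds are only bounds.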

Other observations

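In this part the test of the cell cycle stage was written before its result was seen, and the tests of array scaling and of ERK signalling were chosen after the results were seen. Bootstrap intervals take genes as independent. Members of the Notch, Wnt, BMP and hedgehog pathways changed one by one while camera called none of these lists in any contrast on all 12 arrays. With fry, which does not compare a list with other genes, Notch and hedgehog were called in both differentiation contrasts and Wnt in brain (adjusted p = 0.0211, 0.000301 and 0.00566 in brain, 0.00133 and 3.61e-05 in spinal cord), Notch, Wnt and BMP between proliferative tissues (adjusted p = 0.00317, 0.00996 and 0.0135), Notch and BMP between differentiated ones (adjusted p = 2.49e-06 and 0.0103), and Notch for the difference of responses (adjusted p = 0.000646). The Notch list between differentiated tissues (median -0.72, and -0.31 with dim groups at the floor, camera adjusted p = 0.0618) was called without spinal cord differentiated replicate 1 (adjusted p = 0.0438) or 3 (adjusted p = 0.0467). In brain differentiation 6 Notch genes rose and 4 fell of 18 (7 and 4 adjusted over the list alone; median 0.33, and 0.18 with dim groups at the floor, camera adjusted p = 0.443), with the ligands Dll4 and Jag1 6.42-fold and 4.89-fold lower, and in spinal cord 4 rose and 8 fell (4 and 8 adjusted over the list alone; median -0.25, and -0.07 with dim groups at the floor, camera adjusted p = 0.603), with Nrarp, a target of the pathway, at least 3.06-fold lower. Wnt genes had 8 rises and 4 falls of 19 in brain (8 and 4 adjusted over the list alone; median 0.21, camera adjusted p = 0.329) and 7 and 4 in spinal cord (7 and 5 adjusted over the list alone; camera adjusted p = 0.604), where the median of -0.01 turned positive with either scaling and was 0.33 with dim groups at the floor. Sfrp2, a secreted binder of Wnt ligands, rose 3.95-fold in brain and 6.81-fold in spinal cord, and Wnt7a fell 3.33-fold in spinal cord. BMP genes in spinal cord had 8 rises and 5 falls of 23 (9 and 5 adjusted over the list alone; camera adjusted p = 0.603), with Bmp6 4.56-fold higher and Bmp2 8.52-fold lower. Hedgehog genes had 3 rises and 1 fall of 8 in brain (3 and 1 adjusted over the list alone; median 0.81, and 0.37 with dim groups at the floor, camera adjusted p = 0.28) and 5 and 2 in spinal cord (5 and 2 adjusted over the list alone; median 1.17, camera adjusted p = 0.356). Nkx2-2, a factor of ventral progenitors and oligodendrocytes, rose 6.21-fold in brain and fell 5.34-fold in spinal cord (difference -5.05, limma adjusted p = 3.6e-08), and Smo, the hedgehog signal transducer, rose 3.12-fold in spinal cord.

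Hypoxia and glycolysis genes had 5 rises and 13 falls of 25 in brain differentiation (5 and 13 adjusted over the list alone; median -0.34, camera adjusted p = 0.128), with Vegfa, the vascular growth factor, 3.62-fold and Slc2a3, a glucose transporter, 3.99-fold lower. Between differentiated tissues 13 were higher and 2 lower in spinal cord (13 and 4 adjusted over the list alone; median 0.35, camera adjusted p = 0.124), with P4ha2, a collagen prolyl hydroxylase, 14.8-fold higher (another probe set, dim in brain, was not called at a log2 difference of 2.27). Of 9 neurogenic transcription factors 4 rose and 3 fell in brain differentiation (4 and 3 adjusted over the list alone; median -0.21, and 0.19 with dim groups at the floor, camera adjusted p = 0.677), and Myt1 rose 2.67-fold there and fell 9.94-fold in spinal cord. Endothelial genes had 1 rise and 4 falls of 9 in each tissue (1 and 4 adjusted over the list alone in each; medians -0.47 and -0.20, and -0.08 and 0.000322 with dim groups at the floor, camera adjusted p = 0.361 and 0.704). Of 3 erythroid genes 0 were called in brain differentiation (median -0.23, camera adjusted p = 0.692).

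In brain differentiation 8 mitosis genes rose while 15 DNA replication genes fell. Quantile normalization shifted the change over all probe sets by only -0.06 in brain, so a called list was likely to stay called. Array scaling of the size it removes was argued against for the fall, since the replication list then kept its call with a median of -0.77 (bootstrap interval -0.87 to -0.45, camera adjusted p = 0.00373). On the deposited scale that list lost its call with an estimated correlation (camera adjusted p = 0.605). For the rise it stays open: the median of the mitosis list, uncalled at 0.36, was 0.23 after quantile normalization (interval 0.08 to 0.49, camera adjusted p = 0.0612) and 0.21 after median centring. A later average cell cycle stage of the dividing cells may be part of it: further G2/M genes outside the fixed lists had a median change 0.80 above that of further S phase genes (interval 0.55 to 1.06, and 0.69 to 0.92 leaving out 1 array at a time). These lists had estimated correlations of 0.57 and 0.67, with which neither was called (camera p = 0.788 for G2/M and 0.36 for S phase). Most of that gap came from the S phase genes, of which 25 of 40 fell (median -0.66), while 4 of 37 further G2/M genes rose and 2 fell (median 0.14), so fewer cells in S phase without more in mitosis stays open. The fixed G2/M score minus the S score was -0.50 ± 0.43 in proliferative and 0.49 ± 0.03 in differentiated brain cultures, and 0.42 ± 0.09 and 0.18 ± 0.02 in spinal cord, each with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give.

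Immediate early genes fell as a list in both tissues, but not every member did. Fos had a response difference of -2.56 (limma adjusted p = 6.1e-08), more negative than its own change in spinal cord, so it did not fall in brain. Array scaling of the size that quantile normalization removes was argued against, since the immediate early list kept its call after that step. Its median was then -1.08 in brain (bootstrap interval -1.56 to -0.43, camera adjusted p = 0.000411) and -0.44 in spinal cord (interval -0.97 to -0.13, camera adjusted p = 0.00735). The step shifted the change over all probe sets by only -0.06 in brain and 0.05 in spinal cord, so kept calls were likely beforehand. On the deposited scale the list lost the call with an estimated correlation (camera adjusted p = 0.0628 and 0.174). A candidate explanation is lower ERK signalling in the differentiated cultures: ERK feedback and target genes had a median change of -1.80 in brain, where 20 of 23 fell and 0 rose, and -1.14 in spinal cord, where 16 fell and 1 rose. Without 4 members whose falls had been seen before the list was written, the medians of the 19 left were -1.34 and -1.14. The media of both states are not given in the sources used here, so a difference in added growth factors stays open and untested.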
